A study of Mus musculus with 30 samples.

How the data were processed

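Per the labels, an inducible Cre active in the intestine was used for the deletion, total RNA was isolated, and its biotin-labelled product was put on the arrays. The deposited values are log2 expression values of 45101 probe sets on each of 30 arrays, between 2.64 and 15.21. Neither the labels nor the file headers state how the authors normalized and summarized them. Medians were 6.28 to 6.34 in villus arrays and 6.67 to 6.73 in crypt arrays, and a pair of arrays of the same tissue shared 285 to 596 identical values while a pair of different tissues shared at most 1. The tissues were therefore treated as normalized separately, and the planned test of control crypts against control villi was not run.

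Gene symbols came from the platform annotation given with the data, in which 34958 probe sets have 1 symbol, 932 have several and 9211 have none, and no gene was named from a probe set with several. The gene IDs of 34754 named probe sets were found in a reference gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other, since the files name no build. Each of 18194 genes with a probe set of its own was represented by the one with the highest mean, and the 14548 genes with a mean above the 30th percentile (5.33) were tested.

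Within each tissue a linear model over its 3 genotypes was fitted with limma 3.58.1 in R 4.3.3, without covariates, and moderated p-values were adjusted by Benjamini and Hochberg at 0.05, two-sided. The difference between tissues in the effect of Rb loss, or of Myc loss on top of it, was tested as an interaction over all arrays. The number in the labels was checked for pairing. Villi and crypts of the same genotype and number deviated together from their group means in 15 of 15 cases (r from 0.246 to 0.560, median 0.418), 14 of the 15 correlated best with their own number, and Xist gave the same sex in 15 of 15. They were taken as the same animal, and the interaction with the animal as a block stands beside the one without it. By Xist, controls 1 and 4, Rb KO 3 and DKO 4 and 5 were female.

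In all, 34 lists of genes were fixed, for the cell cycle, Myc-regulated growth, epithelial functions, the cell types of the intestine and its neighbours, and stress and handling. They hold 914 entries, of which 809 have a probe set of their own, 14 through an older symbol, and 773 were measured, 8 of them a second symbol of a gene already in the list, which was counted once. The list of replication-dependent histones, with 1 measured member of 25, was not analysed here. The other 33 were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose p-values depended on the order of the columns in the design, so both orders were run. A list's score is the mean of its members on an array minus the control mean of the tissue, and scores were compared with exact permutation tests over the 252 ways to choose 5 of 10 arrays, two-sided, whose smallest p is 0.00794.

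The genes named were chosen by rule: Rb1 and Myc, the 10 of largest difference in each direction among those past the threshold whose groups of 5 arrays were fully apart and which carry a proper gene symbol, and the 4 members of smallest p of each list called by camera or with 3 or more members past the threshold. The text takes fewer of these, in order, and says where a gene was picked after its values were seen. The lists, the tests, this rule and the first alternatives were chosen before the data were examined. The first alternatives were other ways to join probe sets, other filters, quantile normalization, centring, other sets of arrays in the fit, other settings of limma, the replicate number as a block, sex as a covariate, stricter thresholds, and leaving out each replicate in turn. A crypt marker score and a clock index as covariates, and leaving out control animals 1 and 4 or Rb KO animals 4 and 5, were added afterwards. The crypt marker score is the mean of Olfm4, Lgr5, Ascl2, Smoc2, Slc12a2, Lyz1, Mmp7, Ang4 and Itln1 minus the mean of the tissue, and the clock index is the mean of Arntl, Npas2, Nfil3 and Clock minus that of Dbp, Per2, Per3, Tef and Nr1d2, minus the mean of the tissue.

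Chance in comparisons that share arrays was read from splits of the shared arrays and, for correlations, from simulations without effects too. The fits were tested on simulated data with 200 of 14548 genes changed, 100 by each fold. Of genes changed 1.5-fold, 75% to 90% were recovered in the genotype comparisons and 67% and 69% in the interactions, and of genes changed 2-fold 94% to 99% and 91% and 92%, with 6 to 12 false calls. A list shifted by 0.5 was called and 0 of the other 32 were, which does not test calls of lists whose members correlate. Figures were drawn with matplotlib 3.10.9.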

Results

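Gene expression was measured with arrays in the small intestine of mice 2 months old, 5 days after conditional ablation of Rb1, the gene of the retinoblastoma protein, or of Rb1 together with Myc. Villi, which carry the differentiated epithelium, and crypts, which hold the dividing cells, were profiled separately in control, Rb knockout (Rb KO) and Rb/Myc double knockout (DKO) mice. Each of the 6 groups held 5 arrays, 30 in total. Values are log2, and 14548 genes were tested. The correlation of a pair of arrays of the same group lay between 0.987 and 0.9973. The number of arrays limits the precision, and since the labels do not say that replicates were separate animals, each p-value measures the spread between these samples. Group levels are given as log2 mean ± SD with n = 5, differences as log2 ± SE, and adjusted p-values are two-sided limma values. The groups of genes were lists fixed in advance, 33 of them tested with camera, and beside each count of members past the threshold over all genes stands the count adjusted over the list alone.

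The targeted genes were read first. Rb1, which holds back the E2F transcription factors, stood at 9.73 ± 0.45 in control villi, 8.27 ± 0.06 in Rb KO villi and 8.47 ± 0.16 in DKO villi. In crypts the levels were 9.91 ± 0.50 in control, 8.24 ± 0.07 in Rb KO and 8.30 ± 0.24 in DKO. Rb1 fell by 1.46 ± 0.16 in Rb KO villi (adjusted p = 7.0e-06) and by 1.68 ± 0.18 in Rb KO crypts (adjusted p = 2.7e-05). Every Rb KO and DKO array lay below every control array of its tissue. DKO and Rb KO differed in Rb1 by 0.20 in villi (adjusted p = 0.465) and 0.06 in crypts (adjusted p = 0.877). Myc, the transcription factor that drives growth and ribosome production, stood at 10.51 ± 0.23 in control crypts, 10.48 ± 0.41 in Rb KO crypts and 8.88 ± 0.13 in DKO crypts. It fell by 1.60 ± 0.16 from Rb KO to DKO (adjusted p = 1.9e-05). In villi Myc stood at 7.06 ± 0.60 in control, 7.28 ± 0.21 in Rb KO and 6.76 ± 0.17 in DKO. All 5 DKO villus arrays lay below all 5 Rb KO arrays, with a difference of −0.52 (adjusted p = 0.147). Whether the probes of either gene lie in the deleted exons is not known here, so the remaining signal does not measure what was left of it.

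**Figure D1:**
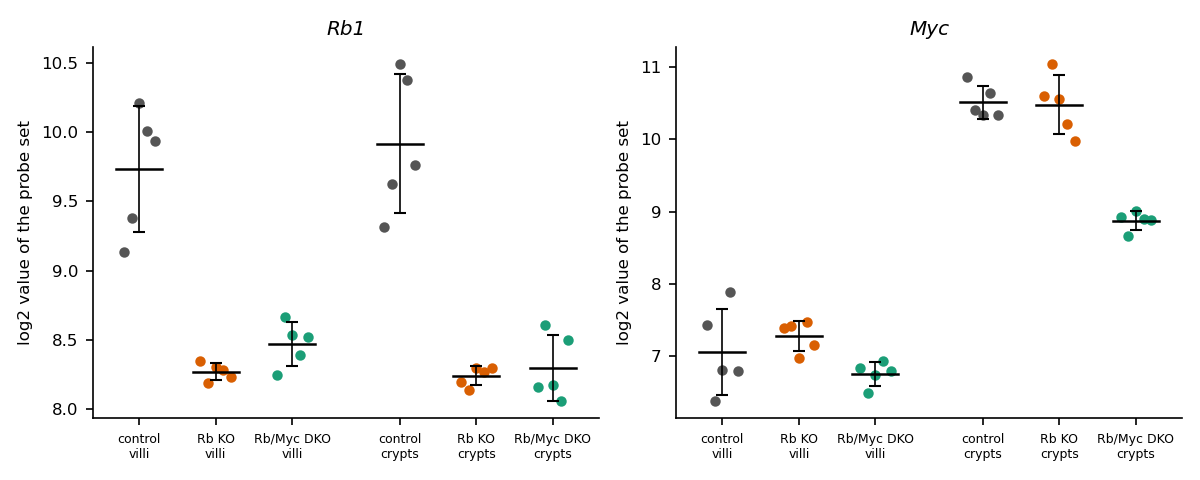
Log2 expression of Rb1 and Myc (y axis) on each of the 30 arrays, in control, Rb KO and DKO villi and crypts (x axis); points are arrays, and bars with error bars are the mean and SD of 5. Rb1 is lower in each Rb KO and DKO group than in its control, and Myc in crypts drops from 10.48 in Rb KO to 8.88 in DKO.

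Villi without Rb carried the transcripts of DNA synthesis and cell division. Rrm2, a subunit of ribonucleotide reductase, rose from 7.04 ± 0.79 in control to 11.18 ± 0.19 in Rb KO villi, a difference of 4.14 ± 0.34 (adjusted p = 2.9e-07). Pcna, the sliding clamp of DNA polymerase, rose from 11.54 ± 0.19 to 13.76 ± 0.10 (adjusted p = 1.2e-09), and Mki67, the proliferation marker Ki-67, from 8.01 ± 0.89 to 11.16 ± 0.27 (adjusted p = 6.0e-06). In all, 4433 genes passed the threshold, 2140 higher and 2293 lower in Rb KO, of which 372 rose and 97 fell at least 2-fold.

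Among the genes with the largest rises, Tcf19, a gene switched on at the start of S phase, rose by 3.91 ± 0.18 and Prim1, the catalytic subunit of DNA primase, by 3.75 ± 0.19. E2f7 rose by 3.64, Pclaf by 3.56, the cyclin gene Ccne2 by 3.56 and Ncapg2 by 3.45. Of 47 measured genes of DNA replication and G1/S, 45 rose and none fell, and 45 rose over the list alone, with a mean difference of 2.07 (camera adjusted p = 6.3e-46; adjusted p = 0.111 with an estimated correlation). Lig1, DNA ligase, rose by 2.77 ± 0.12, and the helicase subunits Mcm6 and Mcm4 by 3.41 ± 0.22 and 2.57 ± 0.12. All 44 measured genes of G2/M and mitosis rose, 44 also over the list alone, by a mean of 1.69 (camera adjusted p = 3.1e-24; adjusted p = 0.737 with an estimated correlation). Among them the kinetochore gene Ndc80 rose by 1.23, the condensin gene Ncaph by 1.87 and the mitotic kinase Cdk1 by 2.95 ± 0.35. In the E2F and pocket protein family of 21 genes 15 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.3e-06; adjusted p = 0.295 with an estimated correlation). Rbl1, the gene of the pocket protein p107, rose by 1.21 ± 0.08, Tfdp1, the partner of the E2F proteins, by 1.49 ± 0.12 and E2f1 by 1.62 ± 0.16.

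Lists of genes that Myc is known to regulate were higher in villi without Rb, with a part of their members past the threshold. Of 50 ribosome biogenesis genes 15 rose and none fell, 16 and none over the list alone, with a mean of 0.37 (camera adjusted p = 3.1e-06; adjusted p = 0.806 with an estimated correlation). Nop56 rose by 1.08 ± 0.22 and Pa2g4 by 0.77 ± 0.16, but their arrays overlapped. So did the list's scores, −0.34 to 0.50 in control and 0.12 to 0.63 in Rb KO. Of 32 translation factors and chaperones 15 rose, 16 over the list alone (camera adjusted p = 6.6e-06; adjusted p = 0.792 with an estimated correlation). Ran rose by 1.19 and its binding protein Ranbp1 by 1.44. In nucleotide, polyamine and one-carbon metabolism 11 of 31 genes rose, and 11 rose and 1 fell over the list alone (camera adjusted p = 9.1e-04; adjusted p = 0.792 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose by 1.59 ± 0.16 and Ctps, CTP synthase, by 1.60 ± 0.18. None of 32 cytosolic ribosomal protein genes passed the threshold by limma, over all genes or the list alone. Their mean rose by 0.24 ± 0.19 (camera adjusted p = 0.0177; adjusted p = 0.806 with an estimated correlation). That call was lost without control 2 (adjusted p = 0.281), control 5 (adjusted p = 0.122) or Rb KO 4 (adjusted p = 0.0601). A score of crypt marker genes, read beside these groups, was −0.390 ± 0.929 in control villi, 0.0614 ± 0.473 in Rb KO villi and 0.329 ± 0.457 in DKO villi. Rb KO and control differed in it by 0.451 (exact permutation p = 0.365, adjusted p = 0.444 over 12 tests). With that score as a covariate, chosen after the values were seen, the mean difference of ribosome biogenesis was 0.206, that of the ribosomal proteins 0.0372 and that of DNA replication 1.95.

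Lists of villus cell functions and of lymphocyte markers were lower, with a part of their members past the threshold. Ubd, a ubiquitin-like protein of the immune response, fell by 2.44 ± 0.48 (adjusted p = 0.00113), the uptake receptor gene Cubn by 2.34 ± 0.36, the glucose transporter family gene Slc5a4a by 2.20 ± 0.26 and the water channel gene Aqp8 by 2.08 ± 0.33. Of 32 brush border enzymes and transporters 14 fell and 1 rose, 15 and 1 over the list alone (camera adjusted p = 0.00241; adjusted p = 0.792 with an estimated correlation). Ace, a peptidase, fell by 1.09 ± 0.18, the peptide transporter Slc15a1 by 0.64 and the peptidase Mme by 0.37. In lipid absorption and metabolism 9 of 28 genes fell, 9 also over the list alone (camera adjusted p = 0.0184; adjusted p = 0.792 with an estimated correlation), among them Hadha, of mitochondrial fatty acid oxidation, by 0.45. The call was lost after quantile normalization (adjusted p = 0.0759), with the mean of all probe sets (0.0785) and without Rb KO animals 4 and 5 (0.125). Acaa2, of the same pathway, fell by 0.45 (adjusted p = 3.5e-04), but 1 of its 3 probe sets had the other sign and the mean of all of them differed by −0.08 (adjusted p = 0.613). Of 21 T cell and intraepithelial lymphocyte markers 13 fell, 14 over the list alone (camera adjusted p = 1.7e-04; adjusted p = 0.792 with an estimated correlation). Itgae, the integrin CD103 of intraepithelial lymphocytes, fell from 10.46 to 9.66 (difference −0.80 ± 0.14, adjusted p = 5.8e-04), Ptprc, the common leukocyte antigen CD45, by 0.62 and the T cell receptor chain gene Cd247 by 0.47. Of 8 class II antigen presentation genes 6 fell, 7 over the list alone (camera adjusted p = 0.0145; adjusted p = 0.792 with an estimated correlation), including H2-DMa by 1.49 ± 0.35 and Ctss by 0.60 ± 0.15. Enteroendocrine markers fell in 6 of 26 cases, 6 also over the list alone (camera adjusted p = 0.00241; adjusted p = 0.792 with an estimated correlation). Gcg, proglucagon, fell from 7.74 to 6.07 (difference −1.68 ± 0.23) and Neurod1, a transcription factor of endocrine cells, by 0.52.

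Cell cycle inhibitors and p53 targets went both ways, 7 of 26 higher and 4 lower (10 and 4 over the list alone), and the list was not called (camera adjusted p = 0.155). Cdkn2c, the CDK inhibitor p18, rose from 7.36 to 9.65 (difference 2.29 ± 0.13, adjusted p = 7.1e-09), and Cdkn1a, the inhibitor p21, from 11.48 to 12.35 (difference 0.87 ± 0.10, adjusted p = 8.8e-06). The log2 difference between 3′ and 5′ probe sets of the GAPDH control transcript, a reading of RNA integrity, was −0.0514 in Rb KO and −0.139 in control villi. It differed by 0.0873 (exact permutation p = 0.00794), and that of Actb by 0.0640 (exact permutation p = 0.0556). With the GAPDH reading as a covariate, chosen after the values were seen, 3313 genes passed and DNA replication genes differed by 2.25. Ribosome biogenesis went from 0.37 to 0.68 (camera adjusted p = 2.1e-13) and ribosomal proteins from 0.24 to 0.60 (camera adjusted p = 4.4e-07), opposite to the crypt marker score as a covariate.

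DKO villi were next compared with Rb KO villi. In DKO villi the mean difference from control was 86.1% of that in Rb KO villi for DNA replication genes, 66.0% for G2/M genes and 30.6% for ribosome biogenesis genes, while the lists of lymphocyte, interferon and endocrine markers were higher. The last share depends on the crypt marker score: with it as a covariate the ribosome biogenesis difference of DKO from control turned from 0.11 to −0.14 (camera adjusted p = 6.9e-05, 13 of 50 lower). That of G2/M went from 1.11 to 0.67, and that of ribosomal proteins from −0.13 to −0.45 (30 of 32 lower). Itgae rose from 9.66 to 10.44 (difference 0.78 ± 0.14, adjusted p = 0.0057), Gcg from 6.07 to 7.33 (difference 1.26 ± 0.23, adjusted p = 0.00523). Bmp4, a secreted signal of the villus mesenchyme, rose from 6.45 ± 0.18 to 8.21 ± 0.38 (difference 1.76 ± 0.17, adjusted p = 1.1e-04). In total 1139 genes passed, 859 higher and 280 lower in DKO (75.4% higher; 65.4% after quantile normalization; 56.4% with the crypt marker score as a covariate, 1438 higher and 1111 lower). The count was 541 to 752 without Rb KO 4 or DKO 2, 3 or 4. The GAPDH 3′ to 5′ difference changed by −0.0436 (exact permutation p = 0.0635) and that of Actb by −0.0439 (exact permutation p = 0.0794).

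Among the genes with the largest rises, Hddc3, a hydrolase, rose from 6.09 ± 0.10 to 9.48 ± 0.41 (difference 3.40 ± 0.46, adjusted p = 8.6e-04). Zfp949 rose by 2.44, Acot1 by 2.04, Fah by 1.92 and Lipo3 by 1.87. The largest falls were in Trim30d (difference −3.39 ± 0.49), Trim34a (−2.70, with 1 of its 2 probe sets called in the other direction) and Trim30a (−2.09), relatives in a family of TRIM genes. Myo7a fell by 1.45 and the carbonic anhydrase Car4 by 1.36 (adjusted p = 0.0237). Control 1 stood with the Rb KO arrays in several of these genes: Trim30d was at 11.54 in control 1, 8.71 in the other controls, 11.49 in Rb KO and 8.09 in DKO villi, and Hddc3 at 6.09, 9.09, 6.09 and 9.48. In crypts Trim30d was at 10.17, 4.83, 10.06 and 4.59 in the same order. Of the 20 genes with the largest differences here, 8 belong to a set of 69 genes in which control 1 stood with Rb KO in both tissues, a set defined after the values were seen: Hddc3, Zfp949, Fah, Sccpdh, Trim30d, Trim34a, Trim30a and Myo7a. The CDK inhibitor gene Cdkn1b, also of that set, rose by 1.17 ± 0.16, with 1 of its 2 probe sets in the other direction, and the cyclin gene Ccnd2 by 1.13 ± 0.23.

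**Figure D2:**
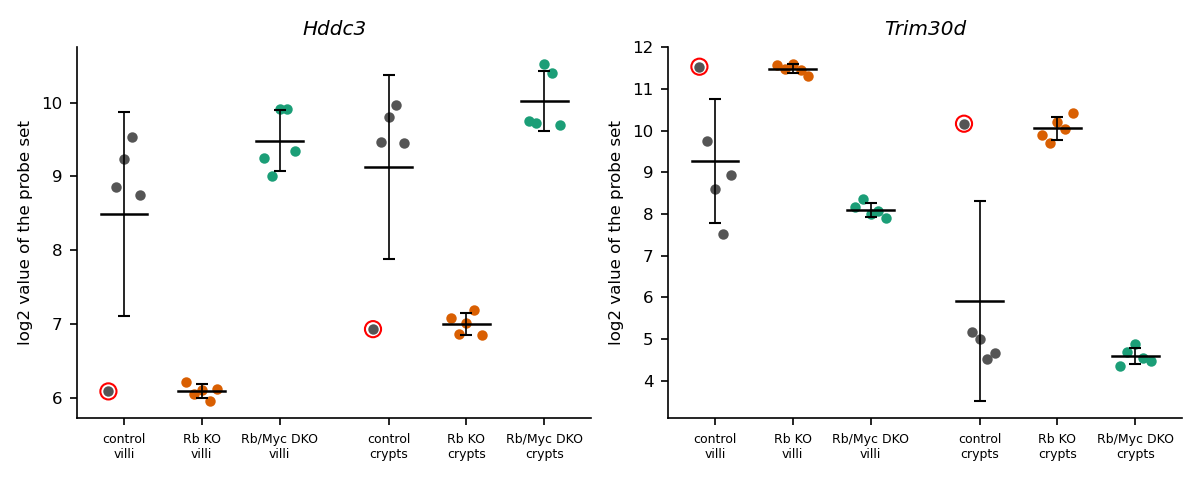
Log2 expression of Hddc3 and Trim30d (y axis) on each of the 30 arrays by group (x axis); points are arrays and control 1 is circled. In villi control 1 lies at 6.09 for Hddc3 and 11.54 for Trim30d, near the Rb KO means of 6.09 and 11.49.

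Genes of cell division were lower as lists, with few members past the threshold. Of 44 G2/M and mitosis genes 3 fell, 3 also over the list alone, with a mean of −0.57 (camera adjusted p = 2.4e-10; adjusted p = 0.648 with an estimated correlation). These were Smc4 (−0.53), Ndc80 (−0.49) and Nuf2 (−0.81). The list's scores overlapped, 1.32 to 2.06 in Rb KO and 0.47 to 1.71 in DKO. So did those of ribosome biogenesis, 0.12 to 0.63 and −0.03 to 0.30. DNA replication had 1 member lower of 47, Fen1 (−0.38 ± 0.09), the flap endonuclease, 1 also over the list alone, and a mean of −0.29 (camera adjusted p = 6.9e-08; adjusted p = 0.648 with an estimated correlation). Smc4, Ndc80, Nuf2, Fen1, Car4 and the incretin gene Gip each lost the call, at adjusted p from 0.0511 to 0.0954, without at least 1 of Rb KO 1, 4 and 5 and DKO 1 to 4, left out singly. In 4 further lists no member passed by limma, over all genes or the list alone. The means were −0.37 for 32 ribosomal proteins (camera adjusted p = 7.1e-08; adjusted p = 0.669 with an estimated correlation) and −0.25 for 50 ribosome biogenesis genes (camera adjusted p = 1.9e-07; adjusted p = 0.691 with an estimated correlation). They were −0.20 for translation factors and chaperones (camera adjusted p = 8.7e-04; adjusted p = 0.693 with an estimated correlation). The mean was −0.15 for nucleotide metabolism (camera adjusted p = 0.0119; adjusted p = 0.693 with an estimated correlation), whose call was lost without Rb KO 4 (adjusted p = 0.0773) or DKO 2 (adjusted p = 0.0595). Cholesterol synthesis had 2 of 19 genes lower, 3 over the list alone (camera adjusted p = 1.7e-04; adjusted p = 0.648 with an estimated correlation).

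These counts and calls depend on settings chosen after the values were seen. With the crypt marker score 39 of 44 G2/M, 24 of 47 DNA replication, 30 of 32 ribosomal protein, 35 of 50 ribosome biogenesis, 15 of 32 translation and 11 of 31 nucleotide metabolism genes were lower. The means were −0.74, −0.36, −0.49, −0.35, −0.29 and −0.22. The cholesterol synthesis call rests on Rb KO animals 4 and 5, whose scores were 0.63 and 0.68 against −0.12 to −0.03 in animals 1 to 3. Without them its mean was −0.0071 (adjusted p = 0.558), that of translation factors −0.07 (0.269) and that of nucleotide metabolism −0.04 (0.435). As a covariate, a clock index, of Arntl and its partners against Dbp and the Per genes, gave −0.11 (0.110), −0.09 (0.140) and −0.04 (0.388) for the same lists.

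Immune and endocrine lists were higher in DKO. Of 27 interferon-stimulated genes 9 rose (13 higher and 1 lower over the list alone; camera adjusted p = 2.0e-07; adjusted p = 0.619 with an estimated correlation). Ifit3 rose by 0.90 ± 0.14, Gbp6 by 0.84 and Usp18 by 0.92. Of 21 T cell markers 7 rose, 13 over the list alone (camera adjusted p = 1.0e-06; adjusted p = 0.619 with an estimated correlation), with Nkg7, of cytotoxic granules, higher by 1.32 and Ptprc by 0.60. Enteroendocrine markers rose in 7 of 26, 9 over the list alone (camera adjusted p = 7.1e-06; adjusted p = 0.619 with an estimated correlation), including the granin gene Scg2 by 0.78 and Gip by 0.69. Of 8 class II genes 1 rose, H2-Oa by 0.68, and 6 over the list alone (camera adjusted p = 0.0014; adjusted p = 0.619 with an estimated correlation). Tuft cell markers rose in 3 of 17, 5 over the list alone (camera adjusted p = 0.00527; adjusted p = 0.619 with an estimated correlation). Of 14 exocrine pancreas genes 3 rose, 3 also over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.619 with an estimated correlation). They included Clps, from 8.73 to 10.04, and Cela1, by 0.71. Single DKO villus arrays scored from −0.41, below every Rb KO array, to 1.43 in this list. Lipid absorption had 4 of 28 members higher, 5 over the list alone (camera adjusted p = 0.031; adjusted p = 0.648 with an estimated correlation). Brush border genes had 2 of 32, 2 also over the list alone (camera adjusted p = 0.0351; adjusted p = 0.691 with an estimated correlation). Genes of the distal small intestine had 1 of 13, with 5 higher and 1 lower over the list alone (camera adjusted p = 0.031; adjusted p = 0.619 with an estimated correlation). The distal list lost its call without Rb KO 1 or 5 or DKO 5 (adjusted p from 0.06 to 0.0728), brush border without Rb KO 1, 4 or 5 or DKO 2 (0.0614 to 0.157), and lipid absorption without Rb KO 1, 4 or 5 or DKO 2 or 3 (0.0585 to 0.112). The clock index separated Rb KO animals 4 and 5 (−1.64 and −1.51 in villi) from animals 1 to 3 (1.24, 0.616 and 0.231). Without these 2 animals 554 genes passed, and the distal, brush border and lipid lists lost their calls (0.125, 0.608 and 0.435), as they did with the index as a covariate (0.0763, 0.354 and 0.266).

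**Figure D3:**
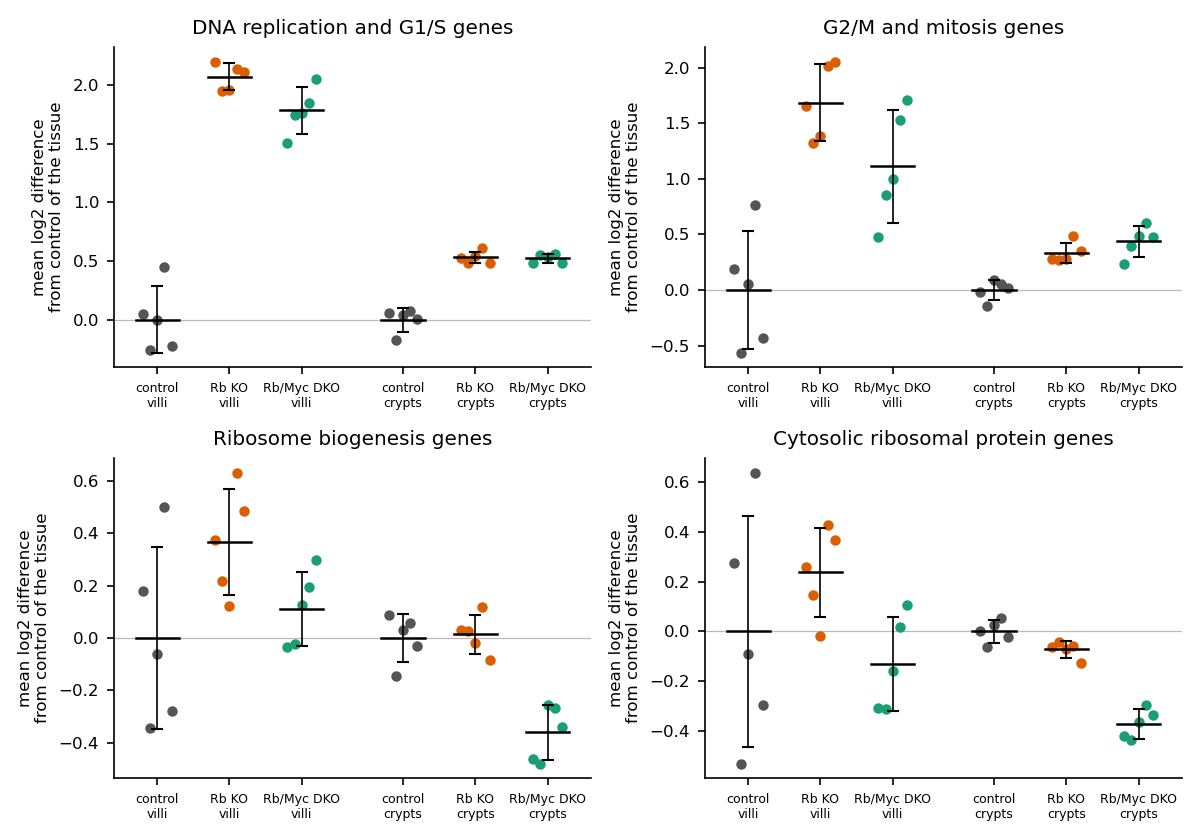
Mean log2 difference from the control mean of the same tissue (y axis) for DNA replication, G2/M, ribosome biogenesis and cytosolic ribosomal protein genes, per array, in control, Rb KO and DKO villi and crypts (x axis); points are arrays, bars the mean and error bars the SD of 5. DNA replication stands at 2.07 in Rb KO and 1.78 in DKO villi, and the ribosome lists in DKO crypts at −0.36 and −0.37.

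The 2 villus comparisons moved in opposite directions. Of the 2140 genes higher in Rb KO than control, 148 were lower in DKO than Rb KO (41.2 for independent lists), and of the 2293 lower ones 609 were higher in DKO (135 for independent lists). Both comparisons use the Rb KO arrays, so opposite calls arise from chance too. In 20 simulations without effects the highest overlap was 0, but with hardly a gene called this cannot measure such chance. With the Rb KO arrays split between the comparisons in 10 ways the counts were 10 to 100 (median 19, against 5.74 for independent lists) and 87 to 308 (median 109, against 23.7). The splits cannot tell loss of Myc from background or RNA integrity that sets Rb KO apart. The GAPDH reading was −0.139 in control, −0.0514 in Rb KO and −0.0950 in DKO. Across genes the differences of Rb KO from control and of DKO from Rb KO correlated at r = −0.609, against −0.499 in simulations without effects and −0.588 to −0.327 in the splits. Their covariance was −0.0640 against −0.00918 simulated, a difference of −0.0549; genes are not independent replicates. The count of 148 was 62 to 93 without Rb KO 1 or 4 or DKO 1, 2, 3 or 4, and that of 609 was 329 to 397 without DKO 2, 3 or 4.

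DKO villi were then compared with control villi. The DNA synthesis program remained high. Pcna stood at 13.51 in DKO and 11.54 in control (difference 1.96, adjusted p = 4.7e-09). Tcf19 was higher by 3.42 ± 0.18, Prim1 by 3.29, Zfp367 by 3.30 and Brca1 by 3.27. In total 2484 genes passed, 1643 higher and 841 lower (66.1% higher; 55.1% after quantile normalization). Of the 2140 genes higher in Rb KO than control villi, 1318 (61.6%) were also higher in DKO, and of the 2293 lower ones 614 (26.8%) were also lower. As both comparisons use the controls, these were split between them in 20 ways, which gave 595 to 1069 (median 836, against 133 for independent lists) and 156 to 401 (median 247, against 45.1). Simulations without effects gave at most 0 and cannot measure this chance. Over those same genes the median difference from control was 0.51 in Rb KO and 0.38 in DKO for the higher ones, and −0.38 and −0.18 for the lower ones. As these genes were selected on the Rb KO arrays, selection alone can make the DKO differences smaller. The differences of Rb KO and of DKO from the shared controls correlated across genes at r = 0.801, against 0.499 in simulations without effects and 0.432 to 0.776 with the controls split. The covariance was 0.112 against 0.00925 simulated, a difference of 0.102.

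Of 47 DNA replication genes 45 rose in DKO villi, 45 also over the list alone, by a mean of 1.78 (camera adjusted p = 1.2e-53; adjusted p = 0.0643 with an estimated correlation), Lig1 by 2.54 and Mcm4 by 2.35. Of 44 G2/M genes 36 rose, 41 over the list alone, by a mean of 1.11 (camera adjusted p = 6.4e-18; adjusted p = 0.907 with an estimated correlation), Mki67 by 2.34 ± 0.34 and Cdk1 by 2.20. The E2F family had 12 higher and 1 lower, 15 and 3 over the list alone (camera adjusted p = 5.4e-07; adjusted p = 0.201 with an estimated correlation). Of 26 cell cycle inhibitors and p53 targets 6 rose and 1 fell, 8 and 1 over the list alone (camera adjusted p = 0.0126; adjusted p = 0.272 with an estimated correlation). Cdkn2c rose by 2.06 and Cdkn1a by 0.74. Interferon-stimulated genes rose in 6 of 27, 7 over the list alone (camera adjusted p = 0.0126; adjusted p = 0.930 with an estimated correlation), Ifit2 by 0.87 and Oas1a by 0.99. Stem cell and Wnt-responsive genes rose in 6 of 28, 6 also over the list alone (camera adjusted p = 0.0222; adjusted p = 0.930 with an estimated correlation). Translation factors rose in 4 of 32, 4 also over the list alone (camera adjusted p = 0.0126; adjusted p = 0.930 with an estimated correlation). Goblet cell markers had 1 of 19 higher, and 0 by limma over the list alone (camera adjusted p = 0.0269; adjusted p = 0.930 with an estimated correlation). Exocrine pancreas genes had 1 of 14 higher, 1 also over the list alone (camera adjusted p = 0.0126; adjusted p = 0.930 with an estimated correlation). The amino acid transporter gene Slc6a20b fell by 1.88, Car4 by 1.86 and the aldolase Aldoc by 1.58. Dbp, an output gene of the circadian clock, fell by 1.87 ± 0.48 (adjusted p = 0.0144), and the clock index was higher in DKO than control villi by 1.67 (exact permutation p = 0.00794, adjusted p = 0.0952 over 12 tests). The crypt marker score was higher by 0.719 (exact permutation p = 0.159, adjusted p = 0.397 over 12 tests) and the GAPDH 3′ to 5′ difference by 0.0437 (exact permutation p = 0.00794), with 0.0201 for Actb (exact permutation p = 0.294). Stem cell genes lost the call without control 2 or 5 or DKO 4 (adjusted p from 0.0504 to 0.0755), translation factors without control 2 (0.269) or DKO 5 (0.0675), and goblet markers without control 3 or 5 or DKO 4 (0.0531 to 0.0894). Interferon genes lost it without control 4 (0.0671), and pancreas genes without DKO 1 (0.102) or DKO 4 (0.0558). With the clock index as a covariate the mean of interferon genes was 0.06 (adjusted p = 0.877), and cell cycle inhibitors and pancreas genes lost the call (0.173 each). The mean of stem cell genes fell from 0.33 to 0.08 (0.676) with the crypt marker score, which is partly made of them. It also ended the calls of translation factors (0.676), goblet markers (0.141) and pancreas genes (0.127).

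In crypts, where cells divide already, genes of the cell cycle were higher in Rb KO than in control. Ccne2 rose from 8.03 to 9.64 (difference 1.61 ± 0.13, adjusted p = 3.3e-06), Ccne1, the other cyclin E gene, by 1.44 ± 0.14 and Tcf19 by 1.26 ± 0.08. Pcna rose from 13.31 to 14.04 (difference 0.73 ± 0.06, adjusted p = 5.0e-06) and Mcm6 from 11.71 to 12.59 (difference 0.88 ± 0.07, adjusted p = 2.3e-06). In total 1498 genes passed, 1066 higher and 432 lower (71.2% higher; 60.1% after quantile normalization), and 21 rose and 18 fell at least 2-fold.

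Of 47 DNA replication genes 40 rose in Rb KO crypts, 43 over the list alone, by a mean of 0.53 (camera adjusted p = 7.8e-43), and the call held with an estimated correlation (adjusted p = 0.0370). Of 44 G2/M genes 29 rose, 38 over the list alone, by a mean of 0.33 (camera adjusted p = 3.0e-22; adjusted p = 0.360 with an estimated correlation). Among the spindle genes Tpx2 rose by 0.46, Nusap1 by 0.55 and Kif4 by 0.47. The E2F family had 9 higher and 3 lower, 12 and 3 over the list alone (camera adjusted p = 3.8e-04; adjusted p = 0.360 with an estimated correlation). Rbl1 rose by 0.55 and E2f1 by 0.69, while Ccnd3 rose by 0.57 with 1 of its 2 probe sets in the other direction. Cell cycle inhibitors and p53 targets rose in 8 of 26 and fell in 1, 9 and 2 over the list alone (camera adjusted p = 0.0129; adjusted p = 0.390 with an estimated correlation). Cdkn1a rose from 10.41 to 11.47 (difference 1.06 ± 0.13, adjusted p = 7.7e-05), Cdkn1c, the inhibitor p57, by 0.97 and Cdkn2c by 0.71. Enteroendocrine markers fell in 5 of 26 and rose in 1, 9 and 1 over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.483 with an estimated correlation). Gcg fell from 9.66 to 8.29, Gip by 0.79 and Ghrl, ghrelin, by 0.98, and Sct, secretin, rose by 0.41. Immediate early genes, which also respond to tissue dissociation, rose in 4 of 22, with 7 higher and 1 lower over the list alone (camera adjusted p = 0.00358; adjusted p = 0.360 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose from 6.56 ± 0.47 to 7.76 ± 0.17 (adjusted p = 5.2e-04) and Jund by 0.25, with 1 of its 2 probe sets in the other direction. The score of the immediate early list was 0.48 to 0.60 in Rb KO animals 1 to 3 but −0.09 and −0.01 in animals 4 and 5, within the −0.31 to 0.28 of control. Cholesterol synthesis genes rose in 4 of 19, 6 over the list alone (camera adjusted p = 0.00599; adjusted p = 0.874 with an estimated correlation). The cholesterol score was 0.48 and 0.38 in Rb KO animals 4 and 5 against 0.0066 to 0.05 in animals 1 to 3, and without these 2 the mean was 0.03 (adjusted p = 0.819). Enpp3, an ectoenzyme, rose by 1.71 ± 0.24 and Myl7, a myosin light chain, from 7.45 ± 0.44 to 8.95 ± 0.17. The protease gene Prss23 fell by 1.62 and the peptide transporter Slc15a2 by 1.60.

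Ribosomal proteins were lower in Rb KO crypts as a list, by a mean of −0.07 with 1 of 32 past the threshold and 0 by limma over the list alone (camera adjusted p = 4.5e-04; adjusted p = 0.874 with an estimated correlation). Stem cell and Wnt-responsive genes had 1 of 28 lower, 1 also over the list alone (camera adjusted p = 0.0143; adjusted p = 0.874 with an estimated correlation). Class II genes had 0 of 8 past the threshold by limma, over all genes or adjusted over the list alone, and a mean of −0.52 (camera adjusted p = 0.00903; adjusted p = 0.758 with an estimated correlation). Class II genes lost the call without control 1 (adjusted p = 0.0736), stem cell genes without control 1 or 4 or Rb KO 4 (0.0695 to 0.107), and cholesterol synthesis without Rb KO 4 (0.0831). As a covariate the crypt marker score ended the calls of cholesterol synthesis (0.490), ribosomal proteins (0.175) and cell cycle inhibitors (0.0523), and, since it is made of 5 stem cell and 4 Paneth cell genes, by construction that of stem cell genes. Rb KO animals 4 and 5 stood apart in crypts too, with a clock index of −1.91 and −1.88 against 0.853, 0.628 and 0.118 in animals 1 to 3. Their level of the heat shock gene Hspa1b was 7.84 and 8.71 against 12.9 to 13.4, and without them 805 genes passed. The crypt marker score differed by −0.213 (exact permutation p = 0.127, adjusted p = 0.397 over 12 tests) and the GAPDH 3′ to 5′ difference by 0.00619 (exact permutation p = 0.611).

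Transcripts of ribosome production were lower in DKO than in Rb KO crypts. Rps6, of the small ribosomal subunit, fell from 10.42 to 9.63 (difference −0.80 ± 0.06, adjusted p = 3.0e-06), and Dkc1, the pseudouridine synthase of rRNA, by 0.65 ± 0.06 (adjusted p = 1.0e-05). Ccnd1, cyclin D1, fell by 0.92 ± 0.12 (adjusted p = 1.2e-04) while Ccnd2, cyclin D2, rose from 11.38 to 13.27 (difference 1.88 ± 0.14, adjusted p = 2.1e-06). DNA replication genes differed by a mean of −0.01, with 2 of 47 lower, 0 by limma over the list alone, and the list was not called (camera adjusted p = 0.992). In total 1802 genes passed, 752 higher and 1050 lower in DKO (41.7% higher; 48.8% after quantile normalization, 34.4% after centring and 51.5% of those changed 1.5-fold).

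Of 50 ribosome biogenesis genes 41 fell and none rose, 47 and none over the list alone, by a mean of −0.38 (camera adjusted p = 1.0e-31; adjusted p = 0.316 with an estimated correlation). Gnl3, nucleostemin, fell by 0.77, Polr1b, a subunit of RNA polymerase I, by 0.68 and the assembly factor Rrs1 by 0.66. Of 32 cytosolic ribosomal proteins 28 fell, 30 over the list alone, by a mean of −0.30 (camera adjusted p = 3.3e-25; adjusted p = 0.295 with an estimated correlation). Rpl14 fell by 0.66 and Rps4x by 0.44, the latter with 1 of its 2 probe sets in the other direction. Of 31 genes of nucleotide, polyamine and one-carbon metabolism 11 fell and 1 rose, 15 and 2 over the list alone (camera adjusted p = 2.0e-07; adjusted p = 0.511 with an estimated correlation). The purine synthesis genes Atic and Ppat fell by 0.62 and 0.68, the folate enzyme Mthfd1 by 0.49 and Srm, spermidine synthase, by 0.87. Translation factors and chaperones fell in 12 of 32, with 19 lower and 1 higher over the list alone (camera adjusted p = 5.9e-08; adjusted p = 0.511 with an estimated correlation). The chaperonin subunit Cct5 fell by 0.38 and Eef1e1 by 0.29. Cholesterol synthesis fell in 7 of 19, with 9 lower and 1 higher over the list alone (camera adjusted p = 9.9e-06; adjusted p = 0.511 with an estimated correlation), Mvd by 0.65 and Idi1 by 0.49. Rb KO animals 4 and 5 stood high here too, and without them the cholesterol synthesis genes of DKO against Rb KO crypts differed by −0.14 in place of −0.30, still called, and Idi1 lost its call (adjusted p = 0.0559).

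Of stem cell and Paneth cell markers a part rose in DKO crypts. Of 28 stem cell and Wnt-responsive genes 15 rose and none fell, 18 and none over the list alone, by a mean of 0.33 (camera adjusted p = 3.0e-09; adjusted p = 0.417 with an estimated correlation). Examples are Aqp4 by 0.71, Slc12a2 by 0.52, Ephb3 by 0.64 and Cd44 by 0.74. Of 15 Paneth cell markers 5 rose, 5 also over the list alone (camera adjusted p = 0.00111; adjusted p = 0.511 with an estimated correlation). The antimicrobial ribonuclease Ang4 rose from 13.80 to 14.38 and Itln1, intelectin, by 0.32. The crypt marker score, which holds several of these genes, was higher by 0.298 (exact permutation p = 0.0159, adjusted p = 0.0952 over 12 tests). Tuft cell markers rose in 1 of 17, 8 over the list alone (camera adjusted p = 3.4e-04; adjusted p = 0.511 with an estimated correlation). T cell markers rose in 2 of 21, 6 over the list alone (camera adjusted p = 8.6e-04; adjusted p = 0.511 with an estimated correlation). Interferon-stimulated genes rose in 3 of 27, 4 over the list alone (camera adjusted p = 0.00246; adjusted p = 0.547 with an estimated correlation). Class II genes rose in 1 of 8, 2 over the list alone (camera adjusted p = 0.0221; adjusted p = 0.630 with an estimated correlation). G2/M genes rose in 4 of 44, 2 over the list alone (camera adjusted p = 4.9e-04; adjusted p = 0.772 with an estimated correlation). Exocrine pancreas genes rose in 1 of 14, 1 also over the list alone (camera adjusted p = 0.00564; adjusted p = 0.714 with an estimated correlation). Of 38 oxidative phosphorylation genes 0 passed by limma over all genes or adjusted over the list alone, with a mean of 0.06 (camera adjusted p = 0.00111; adjusted p = 0.714 with an estimated correlation).

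The single genes with the largest differences in DKO crypts were partly those of the villi. Hddc3 rose by 3.02 ± 0.42, Bmp4 by 1.86 ± 0.21 and Rgcc, a regulator of the cell cycle, from 7.20 to 9.94 (difference 2.74 ± 0.22, adjusted p = 2.9e-06). The mast cell proteases Mcpt1 and Mcpt2 rose by 2.80 and 2.58 and the kinase gene Stk39 by 1.97. Trim30d fell by 5.47 ± 0.77, to 4.59 in DKO crypts, under the filter level of 5.33. Ceacam10 fell by 2.96 and Myo7a by 1.78. Again 8 of the 20 largest, Hddc3, Mcpt1, Mcpt2, Stk39, Trim30d, Myo7a, Trim34a and Mreg, belong to the 69 genes in which control 1 stood with Rb KO. Class II genes lost the call without Rb KO 4 (adjusted p = 0.0837) or DKO 5 (0.0803), and pancreas genes without DKO 4 (0.0973). With the crypt marker score the calls ended for cholesterol synthesis (mean −0.09, adjusted p = 0.190), its member Idi1 (−0.30, adjusted p = 0.115), class II genes (0.159) and pancreas genes (0.952). Those of Paneth cell markers (mean 0.04, adjusted p = 0.221), Slc12a2 (0.0667), Ephb3 (0.0624), Cd44 (0.116), Ang4 (0.0782) and Itln1 (0.0988) ended too, of which the score holds Slc12a2, Ang4 and Itln1 and 4 of the Paneth genes. Without Rb KO animals 4 and 5, 1135 genes passed. In both tissues 224 genes were higher in DKO than Rb KO and 55 lower, against 0 in other splits of the animals, and the GAPDH 3′ to 5′ difference in crypts was 0.0265 (exact permutation p = 0.254).

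Against control crypts, DKO crypts combined higher DNA replication and mitosis genes with lower ribosome genes. Rrm2 was higher by 1.04 (adjusted p = 1.6e-06) and Rps6 lower, with a difference of −0.99 (adjusted p = 1.3e-07). Ccnd1 fell from 10.23 to 8.86 (difference −1.37 ± 0.12, adjusted p = 1.9e-06). In total 2942 genes passed, 1605 higher and 1337 lower. Of the 1066 genes higher in Rb KO than control crypts 709 (66.5%) were also higher in DKO, and of the 432 lower ones 230 (53.2%) were also lower. With the controls split in 20 ways the counts were 262 to 408 (median 373) and 29 to 111 (median 82.5), each above that for independent lists. The GAPDH 3′ to 5′ difference changed by 0.0326 (exact permutation p = 0.206). Across genes the differences from the shared controls correlated at r = 0.452, against 0.503 in simulations without effects and 0.128 to 0.360 with the controls split. The covariance was 0.0224 against 0.00658 simulated, a difference of 0.0158.

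Of 47 DNA replication genes 41 rose in DKO crypts, 43 over the list alone, by a mean of 0.52 (camera adjusted p = 8.4e-32; adjusted p = 0.108 with an estimated correlation), Pcna by 0.78 and Prim1 by 0.87. Of 44 G2/M genes 42 rose, 44 over the list alone, by a mean of 0.44 (camera adjusted p = 1.2e-24; adjusted p = 0.244 with an estimated correlation), Tpx2 by 0.57 and Ndc80 by 0.67. The E2F family had 12 higher and 1 lower, 14 and 1 over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.156 with an estimated correlation). Of 32 ribosomal proteins 30 fell, 32 over the list alone, by a mean of −0.37 (camera adjusted p = 2.7e-27; adjusted p = 0.116 with an estimated correlation). Of 50 ribosome biogenesis genes 37 fell, 43 over the list alone, by a mean of −0.36 (camera adjusted p = 1.7e-24; adjusted p = 0.244 with an estimated correlation). Examples are Rpl14 (−0.85), Dkc1 (−0.71), Polr1b (−0.74) and Npm1, nucleophosmin (−0.59). Nucleotide metabolism had 14 lower and 3 higher, 15 and 4 over the list alone (camera adjusted p = 2.4e-04; adjusted p = 0.662 with an estimated correlation). Translation factors had 11 lower, 3 higher, 15 and 3 over the list alone (camera adjusted p = 3.1e-04; adjusted p = 0.760 with an estimated correlation). T cell markers rose in 5 of 21, 9 over the list alone (camera adjusted p = 5.0e-04; adjusted p = 0.654 with an estimated correlation), Itgae by 0.58 and Cd7 by 0.44. Stem cell genes rose in 7 of 28, with 10 higher and 1 lower over the list alone (camera adjusted p = 0.00322; adjusted p = 0.728 with an estimated correlation). The polycomb gene Bmi1 rose by 0.37 and the Wnt target Sp5 by 0.83. Enteroendocrine markers fell in 6 of 26, 6 also over the list alone (camera adjusted p = 0.0035; adjusted p = 0.662 with an estimated correlation). Pla2g5 rose from 6.88 ± 0.85 to 9.48 ± 0.62, Rgcc by 2.42, Mboat1 by 1.93 and Bmp4 by 1.89. Car4 fell by 1.77 and Snhg4 by 1.64.

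Whether Rb loss acted differently in villi and crypts was tested as the difference of the within-tissue differences. Genes of DNA synthesis rose far more in villi. Rrm2 rose by 4.14 in villi and 0.97 in crypts, a difference of 3.17 ± 0.37 (adjusted p = 6.9e-07), and Mki67 by 3.14 and 0.47, a difference of 2.68. For Prim1 the difference was 2.89 and for Pclaf 2.88. Ubd differed by −2.63 (−2.44 in villi and 0.19 in crypts) and Cubn by −2.16 (−2.34 and −0.18). In total 1999 genes passed, 984 with a higher difference in villi and 1015 with a lower one, and 2987 with the animal as a block.

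The DNA replication list differed by 1.54, with 45 of 47 members higher in villi and none lower (45 and 1 over the list alone; camera adjusted p = 7.3e-67), and the call held with an estimated correlation (adjusted p = 0.00452). G2/M genes differed by 1.36, with 41 of 44 higher, 43 over the list alone (camera adjusted p = 1.5e-29; adjusted p = 0.360 with an estimated correlation). The E2F family had 9 higher and 1 lower, 10 and 1 over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.139 with an estimated correlation). Ribosome biogenesis had 6 of 50 higher, 6 also over the list alone (camera adjusted p = 2.2e-07; adjusted p = 0.836 with an estimated correlation). Translation factors had 5 of 32 higher, 8 over the list alone (camera adjusted p = 1.2e-06; adjusted p = 0.836 with an estimated correlation). Nucleotide metabolism had 6 of 31 higher, 7 over the list alone (camera adjusted p = 1.7e-04; adjusted p = 0.836 with an estimated correlation). Stem cell genes had 4 of 28 higher, 6 over the list alone (camera adjusted p = 0.0271; adjusted p = 0.836 with an estimated correlation). Of 32 ribosomal proteins 0 passed by limma over all genes or adjusted over the list alone, with a mean of 0.31 (camera adjusted p = 1.5e-04; adjusted p = 0.843 with an estimated correlation). T cell markers were lower in villi than in crypts in 9 of 21, 13 over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.594 with an estimated correlation). Brush border genes were lower in 9 of 32, 10 over the list alone (camera adjusted p = 1.3e-04; adjusted p = 0.836 with an estimated correlation). Lipid absorption had 1 of 28 lower, and 0 by limma over the list alone (camera adjusted p = 0.0133; adjusted p = 0.836 with an estimated correlation). Lipid absorption lost the call without control 4 (adjusted p = 0.12) or Rb KO 5 (0.114), and stem cell genes without Rb KO 4 (0.155).

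Despite these differences in size, many genes moved the same way in both tissues. In both tissues 798 genes were higher in Rb KO than control and 256 lower, against at most 3 and 1 in other splits of the animals, while 2 were higher in villi and lower in crypts and 8 the reverse. Across genes, which are not independent replicates, the Rb KO differences of villi and crypts correlated at r = 0.581. In 100 draws without effects the shared animals gave 0.244 to 0.596, so r does not stand out, but a covariance of at most 0.0176, against 0.0511.

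**Figure D4:**
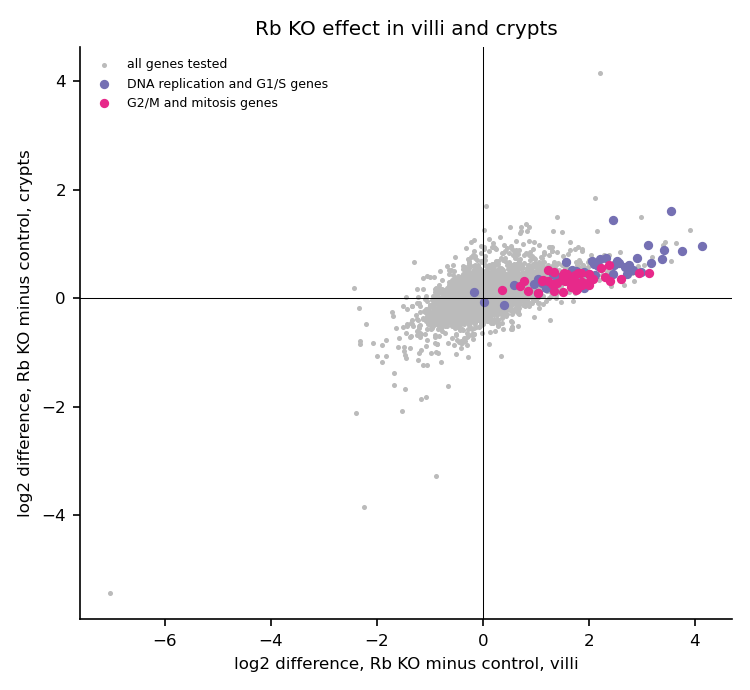
Log2 difference of Rb KO from control in villi (x axis) and crypts (y axis); each point is a gene, all 14548 in grey, DNA replication genes in purple and G2/M genes in pink. The replication genes lie to the right of 0 with a mean of 2.07 in villi and 0.53 in crypts.

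Loss of Myc was tested in the same way. Rgcc rose more in crypts (0.78 in villi and 2.74 in crypts, difference −1.96, adjusted p = 3.0e-04), as did Etv4, an ETS transcription factor (−0.04 and 1.21, difference −1.25), and Tcf23 (difference −1.24, adjusted p = 0.0158). Vnn1, a pantetheinase, was higher in DKO villi but not in crypts (1.64 and −0.26, difference 1.90, adjusted p = 0.0139), and so was the cytochrome P450 gene Cyp2c29 (1.76 and −0.05, difference 1.81, adjusted p = 0.0431). Enpp3 fell in crypts (0.09 in villi and −1.46 in crypts, difference 1.55, adjusted p = 0.0054). In total 495 genes passed, 333 with a higher difference in villi and 162 with a lower one, and 1291 with the animal as a block.

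G2/M genes had a lower difference in villi than in crypts, by a mean of −0.68 with 3 of 44 members past the threshold and 5 over the list alone (camera adjusted p = 9.9e-15; adjusted p = 0.926 with an estimated correlation). DNA replication differed by −0.28 with 0 of 47 past the threshold by limma over all genes or adjusted over the list alone (camera adjusted p = 1.4e-07; adjusted p = 0.926 with an estimated correlation). Enteroendocrine markers differed by 0.33 with 0 of 26 by limma over all genes and 6 over the list alone (camera adjusted p = 0.00272; adjusted p = 0.926 with an estimated correlation). Interferon-stimulated genes had 1 of 27 higher, 3 over the list alone (camera adjusted p = 0.0363; adjusted p = 0.926 with an estimated correlation). Distal intestine genes had 0 of 13 by limma over all genes or adjusted over the list alone and a mean of 0.54 (camera adjusted p = 0.0452; adjusted p = 0.926 with an estimated correlation). Stem cell genes had 0 of 28 by limma over all genes and 2 lower over the list alone (camera adjusted p = 0.0315; adjusted p = 0.926 with an estimated correlation). Of all genes, 2914 had an unadjusted p under 0.05. The count of 495 was 196 to 286 without Rb KO 2, 3 or 4 or DKO 1, 3, 4 or 5. The distal list lost its call without Rb KO 1 or 5 or DKO 3, 4 or 5 (adjusted p from 0.066 to 0.19), interferon genes without Rb KO 4 or 5 or DKO 3 (0.117 to 0.348), and stem cell genes without Rb KO 4 (0.218) or Rb KO 5 (0.0633).

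Of the 33 lists tested, 10 were called in no comparison, with lowest camera adjusted p-values from 0.0687 to 0.527. They hold enteric neuron and glia, B and plasma cell, macrophage and dendritic cell, smooth muscle and fibroblast, and endothelial and red blood cell markers, circadian clock genes, MYC network genes, aryl hydrocarbon receptor targets, enterocyte transcription factors and genes of the proximal small intestine.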

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

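The interactions and the search for arrays that stand apart were planned. Other splits and the tests of the 3 patterns were chosen after the results were seen.

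For each of 11 counts of genes, the same arrays were divided into groups of the same sizes in 100 ways. Each time 1 of 100, the real one, gave as many genes, which argues against chance in how the arrays were grouped. For the villus overlaps, 148 and 609, such splits end the genotype effects and cannot measure opposite calls from the shared Rb KO arrays. The real count and the highest of the others were 4433 and 2041 for Rb KO against control villi, 1139 and 7 for DKO against Rb KO villi, and 2484 and 968 for DKO against control villi. In crypts they were 1498 and 44, 1802 and 3, and 2942 and 11 in the same order. They were 1999 and 1 for the interaction of tissue with Rb loss, 495 and 1 for that with Myc loss, 798 and 3 for genes higher in Rb KO in both tissues, 148 and 0 for villus genes higher and then lower, and 609 and 1 for those lower and then higher. The split with 2041 genes exchanged Rb KO 2 with control 4, that with 1993 Rb KO 3 with control 4, and that with 968 set control 4 with DKO 2 to 5. Control 4 had the highest crypt marker score of the control villi, 0.925.

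By the interaction, the effect of Rb loss differed between villi and crypts in 1999 genes. The mean difference of effects was 1.54 for DNA replication, 1.36 for G2/M, 0.568 for the E2F family, 0.352 for ribosome biogenesis, 0.36 for translation factors, 0.311 for nucleotide metabolism, 0.31 for ribosomal proteins and 0.318 for stem cell genes. It was −0.543 for T cell markers, −0.38 for brush border genes and −0.308 for lipid absorption. For single genes it was 3.17 for Rrm2, 2.89 for Prim1, 2.88 for Pclaf, 2.68 for Mki67, −2.63 for Ubd and −2.16 for Cubn. The effect of Myc loss differed in 495 genes, by 1.9 for Vnn1, 1.81 for Cyp2c29, 1.55 for Enpp3, −1.96 for Rgcc, −1.25 for Etv4 and −1.24 for Tcf23. The lists differed by 0.544 for distal intestine, 0.325 for enteroendocrine markers, 0.262 for interferon-stimulated genes, −0.178 for stem cell genes, −0.28 for DNA replication and −0.679 for G2/M.

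A single array stood apart from the 4 others of its group in 22 of 458 groups tested, 4.80%. By chance about 1 in 20 groups has such an array. The measure is the gap to the nearest other array over the whole range, above 0.71. In Rb KO villi it was 0.81 for Slc5a4a and 0.75 for Mcm4 in replicate 1, 0.723 for Ace and 0.831 for Slc15a1 in replicate 3, and 0.839 for Lig1 and 0.859 for Fah in replicate 4. In DKO villi it was 0.8 for Myo7a in replicate 5. In control crypts it was 0.716 for Prim1, 0.715 for Rps6 and 0.723 for the DNA replication score in replicate 2, and 0.79 for Ghrl in replicate 4. In Rb KO crypts replicate 4 gave 0.84 for Tpx2, 0.868 for Eef1e1, 0.843 for Mvd, 0.741 for the nucleotide metabolism score and 0.882 for the translation factor score, and replicate 3 gave 0.801 for the pancreas score. In DKO crypts it was 0.838 for Rrm2 in replicate 1, 0.729 for Itln1 and 0.771 for the oxidative phosphorylation score in replicate 2, 0.801 for Car4 in replicate 4 and 0.758 for Prim1 in replicate 5.

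The first pattern is the rise of DNA replication and ribosome biogenesis genes in villi without Rb. Crypt cells in the villus samples are a candidate source, since control villi varied in the crypt marker score from −1.33 to 0.925. With that score as a covariate DNA replication kept a mean difference of 1.95 ± 0.08. Crypt cells with the score's markers are thus excluded as its whole cause. Ribosome biogenesis kept 0.206 ± 0.053 of 0.367, and crypt cells stay open there. Crypt cells without these stem and Paneth cell markers were not tested. Sex and RNA integrity are excluded as the whole cause for DNA replication, whose mean difference was 2.12 with sex and 2.25 ± 0.19 with the GAPDH 3′ to 5′ difference as a covariate. A response of villus cells to loss of Rb stays a hypothesis.

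The second pattern is a set of 69 genes, on 18 chromosomes, in which control 1 stood with the Rb KO animals and apart from the other controls in villi and in crypts. An inherited background shared by control 1 and the Rb KO animals may account for it. Of the 69 genes, 25 had another gene of the set within 10 tested genes along the chromosome. Random sets had a median of 6, with a highest count of 22 in 10000 sets and 25 in a further 1000. The sets of the other controls, of 7, 1, 17 and 27 genes, had 0. The definition was the third tried: separation by over 1 log2 gave 4 genes, 2 near another, and separation alone 225, 87 near another (random median 60, highest 90). A mislabelled Rb KO animal is excluded, since Rb1 of control 1 lay 0.793 above the highest Rb KO array in villi and its DNA replication score 1.90 below the lowest. The set holds 31 of the 1139 genes of DKO against Rb KO villi and 30 of 1802 in crypts. For Rb KO against control it holds 59 of 4433 and 28 of 1498. Genes such as Trim30d and Hddc3 cannot be assigned to loss of Myc. The set cannot hold background that sets Rb KO apart from all controls, so the share of background stays unknown.

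The third pattern is a spread of clock genes between animals of the same genotype. Over the 10 control and DKO animals the clock index of villi and crypts correlated at r = 0.842 (permutation p = 0.00219, adjusted p = 0.00486 over 3 relations; rho = 0.794, permutation p = 0.00859; r = 0.625 without the 2 animals farthest from the median), which excludes the handling of single RNA samples as the whole cause. Collection at different times of day is a candidate explanation, as genes of opposite phase correlated at r = −0.822 in villi (permutation p = 0.00324, rho = −0.903), although in crypts at −0.541 (permutation p = 0.11, r = −0.220 without the 2 farthest). Rb KO animals 4 and 5 differed from animals 1 to 3 in this index and in Hspa1b, at 6.31 and 6.43 against 10.6 to 10.9 in villi, a grouping seen in the data and therefore not tested. No biological explanation was tested.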

How the results depend on the processing

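The crypt marker and clock covariates and the removal of 2 animals were chosen after the results were seen. The other alternatives were planned. All 11 counts stayed within 1.5 times under quantile normalization, centring on the median, the stricter percentile filter, no filter, the mean of all probe sets, a fit of only the groups compared, and the trend and robust settings of limma. No scaling reversed a list. Over all alternatives 13601 values of named genes kept direction and side of the threshold, 1144 lost it, 327 gained it and 13 reversed, and for lists 2172 kept it, 271 lost it and 4 reversed. Of 172 named results past the threshold, 6 lost it without 1 replicate and 44 under some other alternative. Crypts were not tested against villi, and log2 values needed no pseudocount. Signal near background shrinks log2 differences, and E2f7 (5.26) and Ifit2 (5.03) in control villi, Lipo3 (5.01) in Rb KO villi and Trim30d (4.59) in DKO crypts lie under the filter level of 5.33, so the sizes of their differences are not exact.

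Counts are given in the order villi Rb KO against control, DKO against Rb KO, DKO against control, then the same in crypts, the interaction with Rb loss, that with Myc loss, the villus genes higher then lower, those lower then higher, and genes higher in Rb KO in both tissues. The cause of a difference was not tested unless fewer arrays or a stricter threshold give it. With every probe set tested on its own they were 8332, 2015, 4139, 2261, 2879, 4698, 3906, 780, 307 and 1093 without the last. At adjusted p under 0.01 they were 2867, 251, 1294, 673, 745, 1648, 940, 85, 24, 143 and 427, and with a change of at least 1.5-fold 1365, 270, 759, 210, 272, 394, 780, 149, 18, 129 and 125. With all 30 arrays in 1 fit DKO against Rb KO villi gave 2054, Rb KO against control crypts 947, DKO against Rb KO crypts 1171, and the villus overlaps 411 and 964. Array weights gave 1054 for the interaction with Myc loss and 262 for villus genes higher then lower, and sex as a covariate 242 for the latter. The crypt marker score as a covariate gave 2549 for DKO against Rb KO villi, 1270 for the interaction with Rb loss and 645 for villus genes higher then lower. The clock index gave 748 for DKO against Rb KO villi and 91 and 383 for the villus overlaps. Without control animals 1 and 4 there were 286 villus genes higher then lower. Without Rb KO animals 4 and 5 there were 554 in DKO against Rb KO villi, 805 in Rb KO against control crypts, 1135 in DKO against Rb KO crypts, 1069 and 276 in the interactions, 92 and 310 in the villus overlaps and 489 in both tissues.

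Without 1 replicate the counts ranged, in the same order, from 3732 to 4769, 541 to 946, 1868 to 2812, 1035 to 1640, 1287 to 1589, 2495 to 2831, 1476 to 2105, 196 to 447, 62 to 198, 329 to 659 and 577 to 810. Numbers shared across genotypes did not pair the arrays, with r from −0.197 to 0.419 in villi and −0.274 to 0.404 in crypts, where 4 and 2 of 15 correlated best with their own number. With the number as a block the counts were 4680, 1354, 2648, 1452, 1701 and 2817, and 211, 712 and 769 for the overlaps. The paired interactions with the animal as a block gave 2987 and 1291, and that block ended no call of a named gene or list in them. The test fry called 11, 6, 4, 5, 9 and 13 lists in the genotype comparisons and 4 and 0 in the interactions, but 0 in place of 6 for DKO against Rb KO villi with the columns of the design turned.

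These values reversed, the cause was not tested, and none of them passed a threshold but the last. Myc in Rb KO against control crypts turned positive with array weights (0.0776), sex (0.0001), the crypt marker score (0.21) or the clock index (0.0554) as a covariate, without control animals 1 and 4 (0.12), Rb KO animals 4 and 5 (0.22), control 1 (0.05), Rb KO 4 (0.03) or Rb KO 5 (0.0882), while without Rb KO 2 it was −0.177. In villi Myc turned to −0.0085 with the crypt marker score for Rb KO against control, and to 0.10 without control animals 1 and 4 for DKO against control. Rb1 in DKO against Rb KO crypts turned to −0.0791 with the mean of all probe sets and −0.017 without DKO 2. With the crypt marker score, translation factors in DKO against control villi turned to −0.0269, stem cell genes, of which the score is partly made, in Rb KO against control crypts to 0.018 and in the interaction with Rb loss to −0.0007, and pancreas genes in DKO against Rb KO crypts to −0.0622. Ribosome biogenesis in DKO against control villi, not called before, turned from 0.11 to −0.14 and past the threshold (adjusted p = 6.9e-05).

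Of the list calls made by camera, the planned estimated correlation kept 2 and lost 86, and fry kept 47 and lost 41. Several lists lost their call under other planned settings. In DKO against Rb KO villi brush border genes did with every probe set (0.212) or the stricter filter (0.160), and lipid genes with the mean of all probe sets (0.164) or that filter (0.0806). In DKO against control villi pancreas genes did with all arrays in 1 fit (0.271) and goblet markers with the stricter filter (0.102). In Rb KO against control crypts inhibitors did with every probe set (0.121) and ribosomal proteins with all arrays in 1 fit (0.149), as did G2/M genes in DKO against Rb KO crypts (0.179). Without Rb KO animals 4 and 5, adjusted p in Rb KO against control villi was 0.062 for class II and for brush border genes. It was 0.22 for ribosomal proteins there, and in crypts 0.131 for class II and 0.299 for stem cell genes. Without control animals 1 and 4 cell cycle inhibitors had 0.0547 and interferon genes 0.165 in DKO against control villi. In the interaction with Rb loss the crypt marker score ended the calls of ribosomal proteins (0.232), brush border (0.106) and lipid genes (0.403). In that with Myc loss interferon genes lost theirs with the clock index (0.589) and without Rb KO animals 4 and 5 (0.939).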

Other observations

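The gene groups, chosen after some members had stood out, and the test given here came after the results were seen, so no group has a p-value. Host genes of small nucleolar RNAs carry the guides of rRNA modification in their introns. Of 12 such genes 10 were lower in DKO than Rb KO crypts (mean −0.70) and 11 lower than in control crypts (mean −0.80). Gas5 differed by −0.85 from Rb KO and −1.14 from control, Snhg4 by −1.36 and −1.64, and Snhg6 by −1.17 and −1.12. In Rb KO villi 5 of the 12 were higher than in control and 1 lower (mean 0.46), and in DKO villi 2 were lower than in Rb KO (mean −0.39).

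Of 10 mast cell genes 5 were lower in Rb KO than control villi (mean −0.45) and 2 in crypts (mean −0.66), and 5 were higher in DKO than Rb KO crypts (mean 0.97). Of these Mcpt1, Mcpt2 and Cpa3 belong to the 69 genes in which control 1 stood with Rb KO. The metallothionein genes Mt1 and Mt2, which buffer zinc and copper, differed by −1.51 (adjusted p = 0.00721) and −1.59 (adjusted p = 0.0291) between Rb KO and control villi. The cytosolic chaperone gene Hsp90aa1 was higher by 1.07 in Rb KO villi (adjusted p = 4.0e-06), and 3 of 10 heat shock genes were higher there. H2-Q2, a class I antigen gene of the same 69, differed by −7.04 in villi (adjusted p = 0.0124) and −5.44 in crypts (adjusted p = 0.0342) between Rb KO and control. Its Rb KO levels of 3.44 and 3.64 lie under the filter level of 5.33, so these sizes are not exact.

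One hypothesis was tested: in villi without Rb, loss of Myc may hold back mitotic genes more than replication genes. The G2/M score minus the DNA replication score was −0.669 ± 0.325 in DKO and −0.385 ± 0.273 in Rb KO villi, a difference of −0.284 (exact permutation p = 0.183), with 3 of 5 DKO arrays below all Rb KO arrays and −0.377 with the crypt marker score as a covariate. The spread between 5 arrays a group keeps the question open.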
